A study of Danio rerio with 72 samples.

How the data were processed

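The authors deposited 1 table of values per series, each with 25067 protein-coding genes and 36 libraries. The deposited values are FPKM, fragments or reads scaled to the length of the gene and the total reads of the library, made by the authors. The labels of the authors name FastQC, HISAT, HTSeq and DESeq2 and the genome build GRCz10, with no versions, roles or order. The RNA was amplified in the manner of single-cell libraries and made into NEBNext Ultra libraries, and no molecular identifiers are named, so PCR copies may count as reads. Laser capture takes tissue by position, so a capture holds every cell type that lies in its outline. The annotation at hand belongs to another genome build than the deposited values, so genes are given by symbol as in the tables, without positions.

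The values carry no scaling beyond the library total. Within each table every gene's low values were whole multiples of a single step per library, and the step times the read total was constant within 0.086% (series M) and 0.113% (series Z). Whole reads could therefore be recovered for all 23948 genes above 0 in series M and all 23482 in series Z. In simulation, 95.17% and 94.53% of genes came back exactly. The recovered reads gave the depth of each library, the thinned tables and the limma-voom fits. They also showed that the left muscle library of layer 6 in series Z was the rounded-up mean of those of layers 1 and 10 (the next closest set of 3 libraries shared 0.7823 of its detected genes), and it was left out of every fit. Of the deposited values 0 columns could not be tied to a library.

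FPKM divides every gene by the library total. Where a few genes take most reads, as in muscle, the values of all others are lowered, and in shallow libraries weakly expressed genes drop to 0. Comparisons between tissues that differ in either way shift the middle of all genes, which quantile scaling removes. Both versions are given where they part.

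Each series was fitted alone. Genes with an FPKM of at least 1 in at least 6 libraries were kept (18263 in series M, 16547 in series Z, 15571 in both). limma-trend was run on log2(FPKM + 1) with terms for region and section, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The section term pairs the regions of a section. Each gene had 1 estimate of its spread, shared by all 6 regions. Where the spread differs between regions, the standard error and p-value of a comparison can be too small or too large. The comparisons were the mean of CA, CV and CVP against the mean of N, L and R (CHT against surrounding tissue), N against the mean of L and R, CV against CA, CVP against CA, CVP against CV, and L against R. A layer trend was fitted to the mean of CA, CV and CVP of each section. A joint fit of both series tested the difference of each region comparison between them. All p-values are two-sided. The shared counts stand beside those that independent lists would give (the product of both counts over the genes tested in both). Correlations over sections have exact permutation p-values over all 720 orders.

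The limma camera test compared 23 gene lists with all other genes in each comparison, with a preset correlation between genes of 0.01 and beside it an estimated one, adjusted over the lists of a comparison and series. The lists were neural, skeletal muscle, endothelial, arterial endothelial, venous scavenger endothelial, blood stem and progenitor cell, niche factor, stromal, macrophage, neutrophil, erythroid, thrombocyte, epidermis, notochord and cartilage, cell cycle, ribosomal protein, oxidative phosphorylation, glycolysis and hypoxia, inflammatory, Notch pathway, immediate early and stress, posterior hox, and tailbud. Members missing from the tables were not analysed here. A list's count is of members called over all genes tested, and the count adjusted over the list alone stands beside it. The list level of a library is the mean log2(FPKM + 1) of the members tested in its series.

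Comparisons, lists, thresholds, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, the 10 genes with the largest mean change in each direction among those called in the same direction in both series (clone-style names left out, and where fewer than 5 qualified also the 5 largest called in either series). It added up to 4 members of each list called in both series, or else up to 2 called in 1 series, and a panel of 25 cell type genes whether called or not. The text names a part of these. hbbe3 and the genes of the difference between series come from the same set.

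The alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, quantile scaling, no section term, the number of detected genes as a covariate, the rank of the layer in place of its number, an estimated correlation for the lists, and each section left out in turn. Added after seeing the data were limma-voom on recovered reads, every library thinned to 75000 reads, series M without the CA library of layer 17, and series Z with the averaged library. A further 9 lists, made after the main results were seen, are described with the other observations.

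R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, were used. A simulation with known changes was run with the CV against CA fit. Of 100 genes with a log2 change of 4 it recovered 54% in series M and 65% in series Z, and of 100 with a change of 2 it recovered 4% and 12%, with 7.9% and 2.5% of the calls false. A log2 change of 2 between single regions was therefore mostly out of reach in that simulation. It called 63 genes in series M and 79 in series Z, against 488 and 712 in the real fit. Its adjusted threshold was thus the stricter one, and its recovery does not carry over directly to the real data.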

Results

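RNA carrying poly(A) tails was sequenced from laser-captured pieces of frozen cross-sections through the tail of zebrafish embryos at 52 hours post fertilization. From each section 6 regions were captured by their position after cresyl violet staining. The vascular captures were the caudal artery (CA), the caudal vein (CV) and the caudal vein plexus (CVP), the venous network between them. Together these 3 make up the caudal hematopoietic tissue (CHT), where blood stem and progenitor cells of the embryo settle and expand. The surrounding captures were the neural tissue (N) and the muscle on the left (L) and right (R). The libraries form 2 series, M and Z, with 6 sections each. The sections of series M carry the layer numbers 2, 6, 8, 12, 15 and 17, and those of series Z the numbers 1, 6, 10, 19, 22 and 25. The labels state neither what M and Z stand for nor which embryo a section came from. The p-values therefore measure the spread between sections, and they are too small if sections share an embryo.

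Of 72 libraries deposited, 71 were used. The left muscle library of layer 6 in series Z held, for 7859 of its 7859 genes with reads, exactly the mean of the left muscle libraries of layers 1 and 10, rounded up to a whole read. It was left out, so that L in series Z has 5 libraries and every other group has 6. The reads over protein-coding genes ran from 75007 to 875545 per library in series M, with a median of 315180. In series Z they ran from 91104 to 4009980, with a median of 655694. N libraries held the most detected genes, on average 17013.5 ± 865.9 (SD, n = 6) in series M and 14904.8 ± 2176.9 in series Z. R libraries held 7332.5 ± 1467.1 and 6629.5 ± 2228.3. In muscle the 50 genes with the most reads took 61.6% (L) and 61.7% (R) of the reads in series M, against 10.8% in N. The RNA was amplified and no molecular identifiers are named, so read totals may include PCR copies and bound the counting error only.

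**Figure D1:**
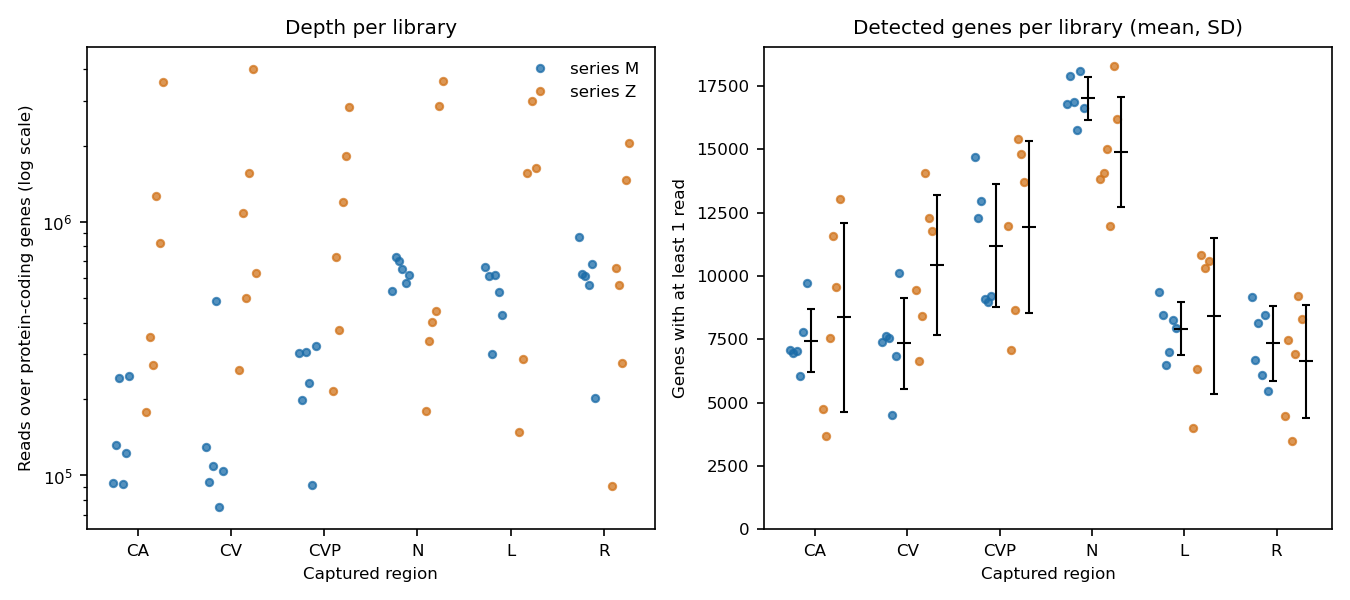
The left panel plots the reads over protein-coding genes (log scale) and the right panel the genes with at least 1 read, for each library by captured region and series, with the mean and SD of the detected genes as bars. Series Z spans 91104 to 4009980 reads and series M 75007 to 875545 reads, and N holds the most detected genes in both.

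In series Z the reads also rose with the layer number. Over the 6 sections, log10 reads in the CHT followed the layer number with Pearson's r = 0.936 (exact permutation p = 0.00972, adjusted over 6 relations p = 0.0194) and Spearman's rho = 0.943 (p = 0.0167). The r for N was 0.895 (exact permutation p = 0.00694) and for muscle 0.912 (p = 0.00833). In series M the CHT gave r = 0.001. Each library's levels over all tested genes were also correlated with the mean of every region, with L and R pooled as muscle. By this measure 32 of 36 libraries of series M and 32 of 35 of series Z lay closest to their own region. The exceptions were all vascular captures. In series M the CA library of layer 8 lay closest to muscle, that of layer 15 closest to CVP, and the CA and CVP libraries of layer 17 closest to CV. In series Z the CVP libraries of layers 22 and 25 lay closest to CV, and the CV library of layer 25 closest to CVP.

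The first comparison asked which genes set the CHT apart from the neural tissue and muscle of the same sections. Changes here and below are differences of log2(FPKM + 1) with the standard error (SE) of limma, over 6 sections a series. That SE rests on 1 spread per gene over all regions, not on the spread of the compared groups alone. Embryonic globins, endothelial genes and stromal genes were higher in the CHT, and contractile genes and respiratory chain genes were lower. hbae3, an embryonic alpha globin, was higher by 3.95 ± 1.00 in series M and by 9.41 ± 0.59 in series Z, in 6 of 6 sections of both. mrc1a, the mannose receptor of venous and lymphatic endothelium, was higher by 4.40 ± 0.56 and 7.02 ± 0.47, again in every section. The fast myosin heavy chain gene myhz2 changed by -3.93 ± 0.41 and -5.56 ± 0.43, and ndufa4, which encodes a respiratory chain subunit, by -4.78 ± 0.54 and -5.16 ± 0.59. The limma test called 1636 genes higher and 1619 lower in series M and 2178 higher and 1453 lower in series Z at an adjusted p under 0.05.

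Among the vascular groups in the CHT, 14 of 19 endothelial genes rose in series M and 19 of 20 in series Z (16 and 19 adjusted over the list alone), with list adjusted p = 1.15e-13 and 9.46e-22. The VEGF receptor gene kdrl rose by 2.87 ± 0.50 and 5.03 ± 0.45, and cdh5, which encodes the cadherin of endothelial junctions, by 4.56 ± 0.44 and 4.46 ± 0.38. In the venous scavenger group, named for endothelium that clears material from the blood, 9 and 11 of 14 genes rose (12 and 12 adjusted over the list alone; list adjusted p = 1.19e-08 and 4.17e-12). Its members included the scavenger receptor gene stab2, up by 3.42 ± 0.58 and 5.16 ± 0.50. Also up were flt4, at 2.18 ± 0.53 and 2.18 ± 0.50, lyve1b, at 1.28 ± 0.45 and 1.99 ± 0.38, and gpr182, at 2.42 ± 0.51 and 4.62 ± 0.52. Of the arterial genes, 5 of 13 and 5 of 12 rose (6 and 6 adjusted over the list alone; list adjusted p = 0.00703 and 0.02). The arterial call in series M was lost at an adjusted p = 0.053 with an estimated correlation. efnb2a, an arterial ephrin, had a change of 1.41 ± 0.54 (adjusted p = 0.065) in series M and rose by 1.76 ± 0.42 in series Z, while the Notch ligand gene dll4 gave 0.23 ± 0.51 (adjusted p = 0.81) and 0.06 ± 0.45 (adjusted p = 0.94).

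Of the erythroid genes, 9 of 16 rose in series M and 17 of 17 in series Z (10 and 17 adjusted over the list alone; list adjusted p = 9.74e-05 and 2.3e-31). The call in series M was lost at an adjusted p = 0.126 with an estimated correlation. alas2, the first enzyme of heme synthesis in red cells, rose by 2.45 ± 0.73 and 7.59 ± 0.57. The erythroid transcription factor gene gata1a had a change of 0.23 ± 0.39 (adjusted p = 0.76) in series M and rose by 3.90 ± 0.52 in series Z. Neutrophil genes rose in 4 of 9 and 10 of 11 cases (6 and 11 adjusted over the list alone; list adjusted p = 0.00663 and 1.47e-09), with adjusted p = 0.0811 with an estimated correlation in series M. mpx, the neutrophil myeloperoxidase, rose by 1.49 ± 0.45 and 3.61 ± 0.43. Of the genes for blood stem and progenitor cells, 3 of 14 and 11 of 18 rose (6 and 11 adjusted over the list alone, with 1 lower in series M; list adjusted p = 0.0111 and 4.33e-06). This call too was lost in series M at an adjusted p = 0.0581 with an estimated correlation. The members called in both series were cebpa, spi1b and myb. myb, a transcription factor of definitive blood progenitors, rose by 1.70 ± 0.51 and 1.97 ± 0.54, in 5 and 6 of 6 sections. Neutrophil genes rose in the same captures, so the list call does not tell stem and progenitor cells from mature blood cells. runx1 did not pass the filter on low values in either series, and hbae1.1 was not analysed here. Thrombocyte genes rose in 2 of 5 and 5 of 8 cases (4 and 6 adjusted over the list alone; list adjusted p = 0.00458 and 5.28e-05). Macrophage genes passed in series Z, with 4 of 10 higher (5 adjusted over the list alone, and 1 lower; list adjusted p = 0.041), and that call was lost at an adjusted p = 0.249 with an estimated correlation. The list adjusted p in series M was 0.14, with 2 of 11 higher, and the difference between the series had a list adjusted p = 0.95. mpeg1.1, a macrophage gene, gave 1.07 ± 0.50 (adjusted p = 0.14) and 0.87 ± 0.46 (adjusted p = 0.18).

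Factors that act on blood stem cells from their surroundings rose in 8 of 13 and 6 of 12 cases (9 and 7 adjusted over the list alone; list adjusted p = 9.51e-06 and 0.00138). The chemokine genes ccl25b, at 3.60 ± 0.74 and 5.65 ± 0.79, and cxcl12b, at 2.84 ± 0.47 and 1.60 ± 0.59, were among them. The transcription factor gene klf6a rose by 2.36 ± 0.53 and 1.89 ± 0.45. cxcl12a rose by 2.21 ± 0.54 in series M and had a change of 0.58 ± 0.52 (adjusted p = 0.48) in series Z. kitlgb, a ligand of the Kit receptor, gave 1.76 ± 0.63 (adjusted p = 0.048) and -0.08 ± 0.52 (adjusted p = 0.94). Of the stromal genes, 15 of 18 and 12 of 19 rose (16 and 16 adjusted over the list alone; list adjusted p = 6.72e-17 and 6.93e-10), among them pdgfra, a growth factor receptor of mesenchyme, by 3.92 ± 0.47 and 3.14 ± 0.43, and the collagen gene col1a1a by 3.60 ± 0.38 and 1.72 ± 0.37.

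On the other side, 20 and 21 of 24 neural genes (20 and 22 adjusted over the list alone) and 22 of 24 muscle genes in each series (22 and 23 adjusted over the list alone) were lower in the CHT. Their list adjusted p were 3.62e-19 and 1.04e-25 for neural genes and 1.16e-26 and 1.05e-34 for muscle genes. The neuronal gene elavl3 fell by 2.37 ± 0.41 and 3.04 ± 0.32, and the actin gene actc1b by 2.59 ± 0.31 and 4.72 ± 0.52. Oxidative phosphorylation genes fell in 72 of 82 and 68 of 85 cases and rose in 0 and 2 (72 and 72 lower adjusted over the list alone; list adjusted p = 2.85e-52 and 5.03e-34). Of the glycolytic and hypoxia genes, 10 and 9 of 16 fell and 1 rose in each series (10 and 10 lower adjusted over the list alone; list adjusted p = 2.56e-07 and 4.54e-06). The calls of the endothelial, venous scavenger, thrombocyte, niche factor, stromal, neural, muscle, oxidative phosphorylation and glycolytic lists held with an estimated correlation in both series.

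Several calls in the CHT rested on the preset correlation. Epidermal genes rose in 9 of 16 and 3 of 15 cases (11 and 3 adjusted over the list alone; list adjusted p = 7.85e-07 and 0.0218), and the adjusted p with an estimated correlation was 0.108 and 0.479. Cell cycle genes rose in 5 of 22 and 5 of 21 cases (5 and 7 adjusted over the list alone; list adjusted p = 0.00456 and 0.00637), with adjusted p = 0.119 and 0.236 with an estimated correlation. Ribosomal protein genes fell in 36 of 88 and 3 of 87 cases, and 1 rose in series M (57 and 0 lower adjusted over the list alone; list adjusted p = 2.28e-15 and 2.49e-05), with adjusted p = 0.0903 and 0.382 with an estimated correlation. Inflammatory genes passed in series Z (5 of 12 higher, 6 adjusted over the list alone; list adjusted p = 0.0417, and adjusted p = 0.122 with an estimated correlation), with 3 of 13 higher and a list adjusted p = 0.0591 in series M, and the difference between the series did not pass (list adjusted p = 0.926). The notochord and cartilage, Notch, immediate early, posterior hox and tailbud lists did not pass in either series, with list adjusted p from 0.0614 to 0.68 in series M and from 0.125 to 0.86 in series Z. shha, a signal of notochord and floor plate, gave -0.21 ± 0.52 (adjusted p = 0.83) and -0.65 ± 0.38 (adjusted p = 0.23).

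Both series shared 851 genes higher and 840 lower in the CHT, against 213 and 136 that independent lists would share, and 5 genes went opposite ways. Quantile scaling moved the share of called genes that were higher from 50.3% to 38% in series M (1151 higher, 1876 lower) and from 60% to 46.2% in series Z (1448 higher, 1683 lower). In series Z it moved the median of all genes from 0.19 to -0.01. With the number of detected genes as a covariate, 2083 genes were called in series M, and limma-voom on recovered reads called 10766.

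**Figure D2:**
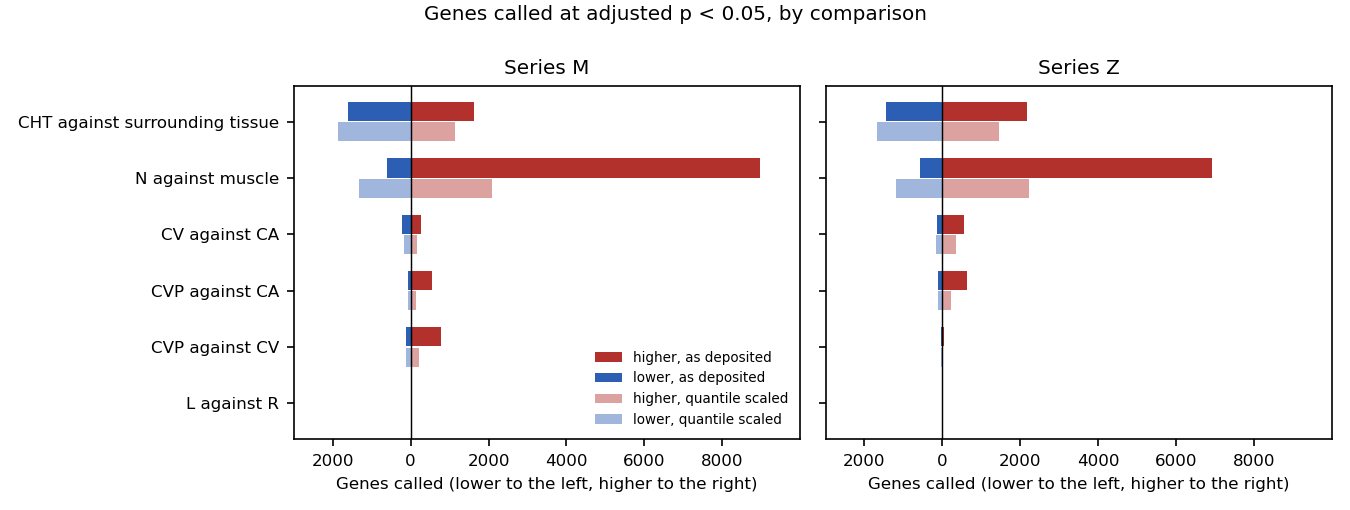
Bars give the genes called at an adjusted p under 0.05 in each comparison and series, lower to the left and higher to the right, for the deposited values (dark) and after quantile scaling (light). N against muscle has 8973 genes higher in series M as deposited and 2076 after quantile scaling.

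The second comparison set the neural tissue against muscle. Neural genes stood far above their level in muscle. elavl3 reached 9.42 ± 0.28 (SD, n = 6) on the log2 scale in N of series M and was listed at 0 in all 12 muscle libraries, and in series Z it was higher by 9.75 ± 0.48. gfap, the intermediate filament of glia, was higher by 9.20 ± 0.81 and 9.06 ± 0.76, in 6 of 6 sections of both series. actc1b fell by 9.16 ± 0.47 and 6.73 ± 0.78 and the myosin light chain gene mylpfa fell by 10.26 ± 0.62 and 6.89 ± 0.84. limma called 8973 genes higher and 598 lower in N in series M, and 6924 higher and 578 lower in series Z.

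All 24 neural genes were higher in both series (24 and 24 adjusted over the list alone; list adjusted p = 1.39e-27 and 2.21e-29), and 23 of 24 muscle genes were lower in both (23 and 23 adjusted over the list alone; 1.1e-82 and 1.5e-51). Notch pathway genes were higher in 16 and 15 of 18 cases, with 1 lower in series Z (17 and 15 adjusted over the list alone; list adjusted p = 6.35e-06 and 1.57e-05). The Delta ligand gene dlb was higher by 7.36 ± 0.63 and 7.52 ± 0.52. Glycolytic and hypoxia genes were lower in 9 and 7 of 16 cases and higher in 3 and 3 (10 and 7 lower adjusted over the list alone; 6.02e-14 and 6.12e-09), with aldolase gene aldoab at -8.50 ± 0.78 and -7.24 ± 1.00. Oxidative phosphorylation genes were lower in 23 of 82 and 29 of 85 cases (16 and 27 adjusted over the list alone; 1.18e-34 and 2.94e-27). Stromal genes were lower in 4 of 18 and 8 of 19 cases and higher in 1 of each series (4 and 8 lower adjusted over the list alone; 5.61e-07 and 4.59e-12), with col1a1a at -2.78 ± 0.57 and -3.98 ± 0.56. The stromal list level in N, L and R was 2.78, 3.28 and 3.08 in series M and 2.92, 4.01 and 4.54 in series Z. A list test sets the list beside all other genes, whose median change was 1.63 and 1.32. A list that changes little can therefore test as lower here. pdgfra gave 1.22 ± 0.70 (adjusted p = 0.14) and 0.37 ± 0.64 (adjusted p = 0.66).

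Keratins of the skin were also lower in N than in the muscle captures. Of the epidermal genes, 9 of 16 and 13 of 15 were lower (9 and 15 adjusted over the list alone; list adjusted p = 8.34e-21 and 1.79e-26), with the surface keratin gene krt4 at -7.50 ± 1.12 and -9.91 ± 0.79, in every section. Ribosomal protein genes were lower in 72 of 88 and 48 of 87 cases and higher in 7 and 4 (73 and 50 lower adjusted over the list alone; 2.77e-57 and 1.98e-34). This list, made from a name pattern, also took in S6 kinase genes such as rps6kc1, which was higher by 3.36 ± 0.62 and 2.69 ± 0.83. rplp0, a protein of the ribosomal stalk, was lower by 2.22 ± 0.26 in series M and 1.45 ± 0.22 in series Z, where quantile scaling turned its change to 0.31. Calls of all the lists named so far for N against muscle held with an estimated correlation in both series. For erythroid genes the test was negative (list adjusted p = 0.0212 and 0.0332) while the median was 0.33 and 0.50 and the mean 0.58 and 0.39, and with an estimated correlation the adjusted p was 0.489 and 0.459. With detected genes as a covariate the test in series Z turned positive (list adjusted p = 0.928), with a median of 0.78. The posterior hox list passed in series Z (10 of 13 higher, 11 adjusted over the list alone; list adjusted p = 0.0498, and adjusted p = 0.115 with an estimated correlation), with 7 of 11 higher and a list adjusted p = 0.552 in series M. The other 13 lists gave list adjusted p from 0.121 to 0.973 in series M and from 0.0569 to 0.881 in series Z.

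Both series shared 5511 genes higher and 415 lower in N, against 3460 and 21.4 for independent lists, and 1 gene went opposite ways. The excess of higher genes moved with the scaling. Of the called genes, 93.8% and 92.3% were higher as deposited, and 60.8% and 65.1% after quantile scaling (2076 higher and 1338 lower in series M, 2232 and 1195 in series Z). Quantile scaling moved the median of all genes from 1.63 to -0.11 in series M and from 1.32 to -0.05 in series Z. The size of most single changes in this comparison is therefore relative to that shift, and so are the list tests. With detected genes as a covariate, 438 genes in series M and 1575 in series Z were called.

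**Figure D3:**
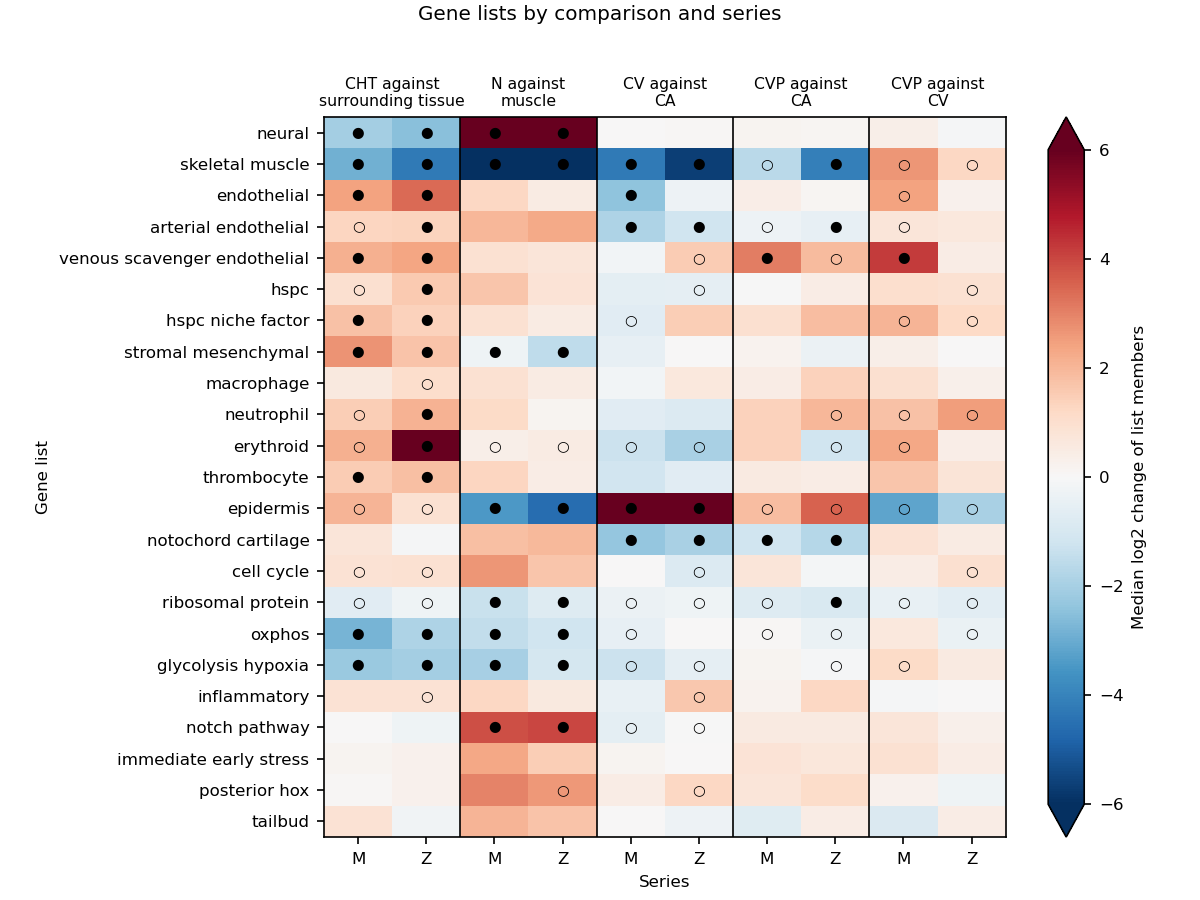
Colour gives the median log2 change of the tested members of each gene list, by comparison and series, on a scale that saturates at 6 in either direction. A filled circle marks a list adjusted p under 0.05 with both the preset and the estimated correlation, and an open circle marks the preset correlation alone.

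Within the CHT, the vein was first set against the artery. Skin keratins and fin fold actinodins were far higher in the CV captures, and muscle genes, notochord genes and both cxcl12 genes were higher in the CA captures. krt4 was higher in CV by 8.46 ± 1.29 in series M, in 5 of 6 sections, and by 9.10 ± 0.90 in series Z, in 6 of 6. The actinodin gene and2, which encodes a fin fold fibre protein, was higher by 9.24 ± 1.06 and 11.75 ± 0.94, in every section. Both genes for the chemokine Cxcl12, which draws blood stem cells to their niche, were lower in CV than in CA: cxcl12b by 6.51 ± 0.81 and 7.14 ± 1.00, and cxcl12a by 6.1 ± 0.93 and 5.84 ± 0.88, in 6 of 6 sections. limma called 257 genes higher and 231 lower in CV in series M, and 564 higher and 148 lower in series Z.

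Epidermal genes were higher in 12 of 16 and 13 of 15 cases (13 and 14 adjusted over the list alone; list adjusted p = 7.41e-24 and 1.08e-29). The epidermal list averaged 8.15 ± 0.79 (SD, n = 6) in the CV of series M and 8.11 ± 0.46 in that of series Z. In layer 17 of series M the CA library reached 8.65 on this list, against 1.13 to 2.62 in the other CA libraries. Muscle genes were lower in 18 and 19 of 24 cases (19 and 22 adjusted over the list alone; 6.43e-36 and 4.3e-52), with actc1b down by 4.34 ± 0.54 and 6.59 ± 0.89. The CA library of layer 8 in series M stood at 10.05 on the muscle list, against 5.79 to 7.22 in the other CA libraries. Notochord and cartilage genes were lower in 4 of 13 and 5 of 12 cases (7 and 6 adjusted over the list alone; 4.2e-09 and 3.53e-11), with the cartilage collagen gene col2a1a down by 6.86 ± 0.86 and 6.52 ± 0.92, and shha listed at 0 in all CV libraries. Arterial genes were lower in 5 of 13 and 2 of 12 cases (8 and 2 adjusted over the list alone, with 1 higher in series M; 2.37e-07 and 0.000559). dll4 fell by 3.11 ± 0.88 and 2.68 ± 0.76, in 5 of 6 sections of both, and efnb2a gave 0.43 ± 0.94 (adjusted p = 0.9) and -1.21 ± 0.71 (adjusted p = 0.42). These 4 lists held with an estimated correlation in both series.

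Endothelial genes as a group were lower in the CV of series M, with 4 of 19 down (12 adjusted over the list alone; list adjusted p = 4.27e-10, and adjusted p = 0.0116 with an estimated correlation). kdrl fell there by 3.79 ± 0.87 and cdh5 by 3.56 ± 0.77. In series Z 0 of 20 passed (2 lower and 1 higher adjusted over the list alone; list adjusted p = 0.0549), and kdrl gave 0.34 ± 0.77 (adjusted p = 0.9). The difference between the series had a list adjusted p = 0.000589, and 0.24 with an estimated correlation. Venous genes passed in series Z with 1 of 14 higher (3 adjusted over the list alone; list adjusted p = 0.00991, and adjusted p = 0.18 with an estimated correlation), and gave a list adjusted p = 0.255 in series M. stab2 gave -0.12 ± 1.01 (adjusted p = 1) and 2.54 ± 0.85 (adjusted p = 0.085), mrc1a -0.62 ± 0.97 (adjusted p = 0.83) and 1.86 ± 0.80 (adjusted p = 0.22), and flt4 -0.60 ± 0.92 (adjusted p = 0.83) and -0.61 ± 0.84 (adjusted p = 0.81). lyve1b was higher in CV by 2.29 ± 0.64 in series Z, in 5 of 6 sections, and was listed at 0 in all CA and CV libraries of series M. Among the niche factors, ccl25b was higher by 6.64 ± 1.33 in series Z and had a change of 1.46 ± 1.27 (adjusted p = 0.65) in series M.

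Other lists passed in CV against CA with the preset correlation alone. Lower in both series were erythroid genes (0 of 16 and 1 of 17 members, 0 and 2 adjusted over the list alone; list adjusted p = 0.0239 and 9.86e-10; adjusted p = 0.525 and 0.0855 with an estimated correlation) and ribosomal protein genes (0 of 88 and 0 of 87 members; 0.00052 and 5.04e-07; adjusted p = 0.552 and 0.345 with an estimated correlation). Glycolytic genes (3 and 2 of 16 lower, 5 and 6 adjusted over the list alone; 0.00731 and 0.00549) gave an adjusted p = 0.0921 and 0.18 with an estimated correlation. Notch genes (2 and 3 of 18 lower, 4 and 3 adjusted over the list alone; 0.0239 and 0.0338) gave an adjusted p = 0.0682 and 0.18 with an estimated correlation. In series M the niche factors (2 of 13 lower, 2 adjusted over the list alone; 0.0215) and oxidative phosphorylation genes (5 of 82 lower, 6 adjusted over the list alone; 0.00744) passed, with an adjusted p = 0.0682 and 0.365 with an estimated correlation. In series Z the cell cycle list (1 of 21 lower, 2 adjusted over the list alone; 0.000135) and the blood stem cell list (0 of 18 called, 1 higher adjusted over the list alone; 0.0338) passed as lower, with an adjusted p = 0.131 and 0.18 with an estimated correlation. Inflammatory genes (2 of 12 higher, 2 adjusted over the list alone; 0.00991) and posterior hox genes (2 of 13 higher, 4 adjusted over the list alone; 0.0148) passed as higher, with an adjusted p = 0.0785 for both with an estimated correlation. The neural, stromal, macrophage, neutrophil, thrombocyte, immediate early and tailbud lists did not pass in either series, with list adjusted p from 0.0549 to 0.915.

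Both series shared 128 genes higher and 63 lower in CV, against 8.66 and 2.06 for independent lists, and 0 went opposite ways. In series Z quantile scaling moved the share of called genes that were higher from 79.2% to 67.4% (355 higher, 172 lower) and the median of all genes from 0.25 to -0.05. The count of series M fell from 488 to 301 without layer 6, to 315 without layer 8 and to 289 with limma-voom, and that of series Z fell from 712 to 466 with detected genes as a covariate.

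**Figure D4:**
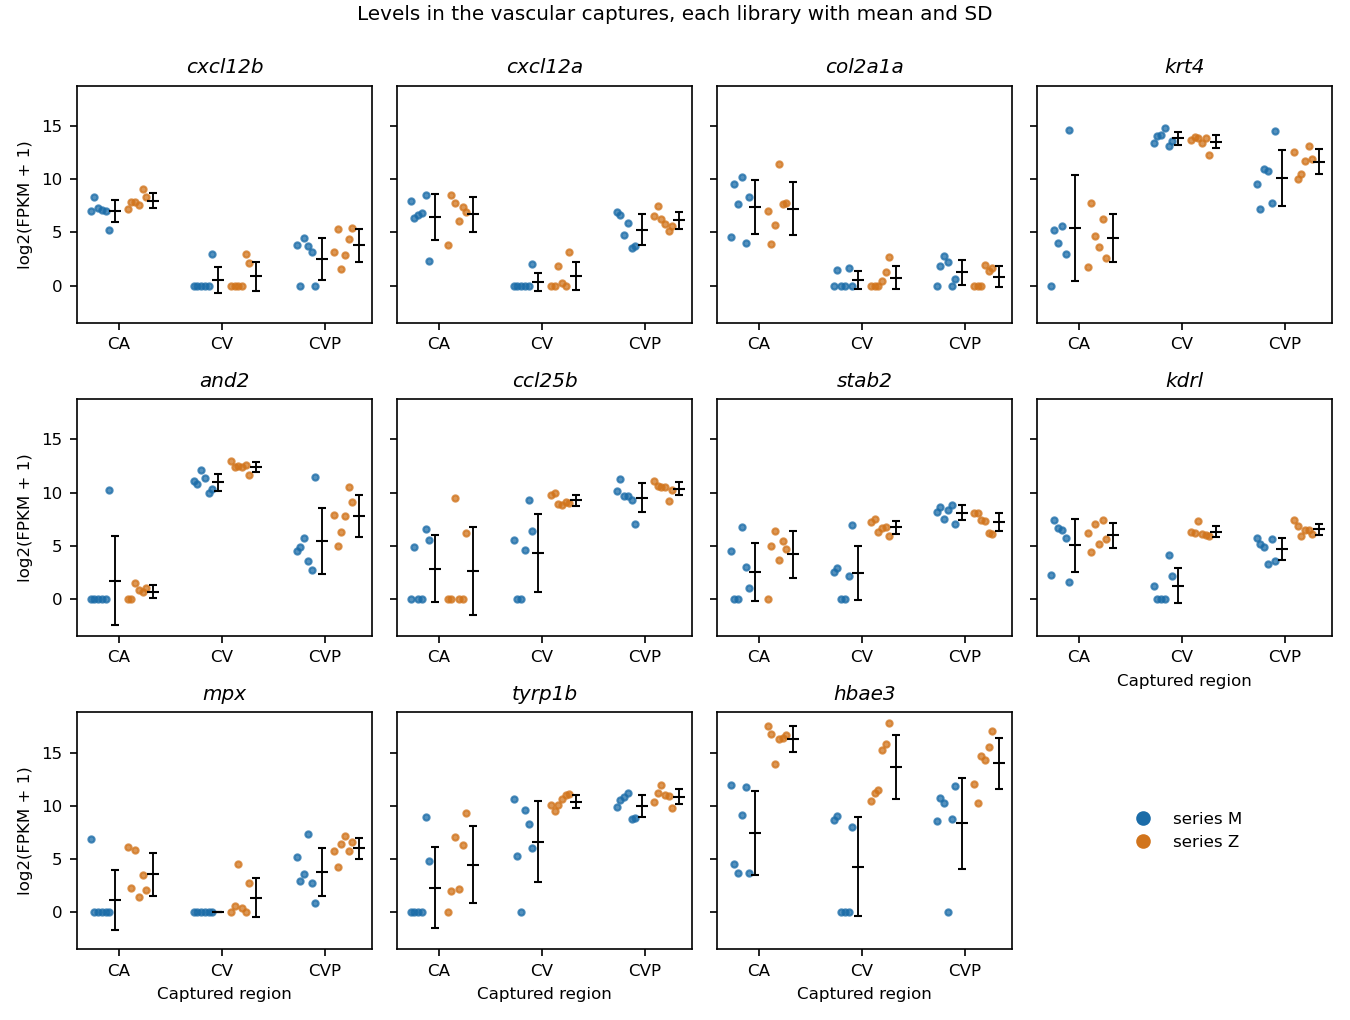
Each panel plots the level of 1 gene as log2(FPKM + 1) in every CA, CV and CVP library of both series, with the mean and SD of the 6 libraries of a group as bars. On average cxcl12b lies at 8.00 in CA and 0.85 in CV of series Z, and krt4 at 13.87 (series M) and 13.53 (series Z) in CV.

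The plexus was then set against the artery. The scavenger receptor gene stab2, the melanin synthesis gene tyrp1b and the niche chemokine gene ccl25b were higher in the CVP captures, and notochord collagen and cxcl12b were higher in CA. stab2 rose from CA to CVP by 5.57 ± 1.01 and 3.03 ± 0.85, in 6 of 6 sections of both series, and ccl25b by 6.68 ± 1.27 and 7.75 ± 1.33, again in every section. tyrp1b was higher by 7.71 ± 1.25 and 6.40 ± 1.48, in 5 and 6 of 6 sections. col2a1a was lower by 6.14 ± 0.86 and 6.39 ± 0.92, and cxcl12b by 4.49 ± 0.81 and 4.21 ± 1.00, in every section, while cxcl12a gave -1.20 ± 0.93 (adjusted p = 0.52) and -0.58 ± 0.88 (adjusted p = 0.77). limma called 547 genes higher and 68 lower in series M, and 620 higher and 117 lower in series Z.

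Venous scavenger genes were higher in 7 and 4 of 14 cases (10 and 9 adjusted over the list alone; list adjusted p = 7.38e-12 and 0.000266), and in series Z the call was lost at an adjusted p = 0.079 with an estimated correlation. lyve1b, a receptor of lymphatic and venous endothelium, was higher by 3.78 ± 0.64 in series Z and was listed at 0 in all CA libraries of series M. mrc1a was higher by 5.12 ± 0.97 in series M and gave 2.49 ± 0.80 (adjusted p = 0.065) in series Z, and gpr182 by 4.01 ± 0.88 and 2.35 ± 0.88 (adjusted p = 0.12). flt4 gave 1.93 ± 0.92 (adjusted p = 0.25) and -0.26 ± 0.84 (adjusted p = 0.91). Notochord and cartilage genes were lower in 4 of 13 and 5 of 12 cases (5 and 6 adjusted over the list alone; 2.34e-09 and 3.45e-10), which held with an estimated correlation in both series. shha gave -0.76 ± 0.91 (adjusted p = 0.7) and -0.72 ± 0.64 (adjusted p = 0.57). Muscle genes were lower in 6 and 17 of 24 cases, with 1 higher in series M (10 and 19 lower adjusted over the list alone; 1.02e-11 and 4.05e-46), and in series M the adjusted p was 0.0887 with an estimated correlation. Arterial genes were lower as a group (0.0147 and 0.00333), with 1 member down and 1 up in series M and 0 in series Z (2 and 1 lower adjusted over the list alone), and in series M the adjusted p was 0.105 with an estimated correlation. dll4 gave -2.43 ± 0.88 (adjusted p = 0.11) and -2.41 ± 0.76 (adjusted p = 0.063).

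Epidermal genes were higher in the CVP in 5 of 16 and 9 of 15 cases (8 and 12 adjusted over the list alone; list adjusted p = 0.00583 and 1.05e-13), with adjusted p = 0.59 and 0.052 with an estimated correlation. The CVP library of layer 17 in series M stood at 8.74 on this list, against 2.89 to 5.89 in the other CVP libraries. Ribosomal protein genes were lower in 6 of 88 and 22 of 87 cases (22 and 63 adjusted over the list alone, with 1 higher in each; 3.56e-31 and 4.08e-51), and in series M the adjusted p was 0.0521 with an estimated correlation. Oxidative phosphorylation genes passed as lower (2 of 82 and 3 of 85, 2 and 2 adjusted over the list alone; 0.000228 and 8.22e-09), with adjusted p = 0.235 and 0.0861 with an estimated correlation. Their median was 0.08 and their mean -0.09 in series M. In series Z the neutrophil (3 of 11 higher, 6 adjusted over the list alone; 0.0021), erythroid (0 of 17 lower; 3.24e-08) and glycolytic (0 of 16 lower; 0.0291) lists passed, with adjusted p = 0.208, 0.123 and 0.26 with an estimated correlation. mpx gave 2.63 ± 0.78 (adjusted p = 0.051) and 2.44 ± 0.73 (adjusted p = 0.047), in 5 of 6 sections of both series. The endothelial list did not pass (list adjusted p = 0.615 and 0.107), and kdrl gave -0.33 ± 0.87 (adjusted p = 0.88) and 0.58 ± 0.77 (adjusted p = 0.73). The other 12 lists gave list adjusted p from 0.16 to 0.904 in series M and from 0.071 to 0.876 in series Z.

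Both series shared 89 genes higher and 18 lower in CVP, against 19.3 and 0.465 for independent lists, and 2 went opposite ways. Of the called genes, 88.9% and 84.1% were higher as deposited, and 65.4% and 64% after quantile scaling (125 higher and 66 lower in series M, 210 and 118 in series Z), which moved the median of all genes from 0.58 to -0.02 and from 0.56 to -0.01. Equal depth lowered the counts from 615 to 320 and from 737 to 463, detected genes as a covariate to 38 and 196, and limma-voom that of series M to 222. Without layer 2, 6, 8 or 12 series M gave 365, 277, 224 or 343 genes, and without layer 1, 10, 19 or 22 series Z gave 405, 475, 439 or 471.

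Last among the vascular captures, the plexus was set against the vein. cxcl12a was higher in CVP, and actinodin genes of the fin fold were higher in CV. cxcl12a was higher in CVP by 4.91 ± 0.93 in series M and 5.26 ± 0.88 in series Z, in 6 of 6 sections of both, while cxcl12b gave 2.02 ± 0.81 (adjusted p = 0.14) and 2.93 ± 1.00 (adjusted p = 0.25). mpx was higher by 4.62 ± 0.73 in series Z, in every section, and in series M it stood at 3.78 ± 2.24 (SD, n = 6) in CVP and was listed at 0 in all 6 CV libraries. The actinodin genes and1 and and2 were lower in CVP, and1 by 5.72 ± 1.32 and 7.08 ± 0.97 and and2 by 5.50 ± 1.06 and 4.64 ± 0.94, in 5 and 6 of 6 sections. limma called 775 genes higher and 120 lower in series M, and 33 higher and 40 lower in series Z.

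The series differed on the venous scavenger list. Venous scavenger genes were higher in the CVP of series M in 8 of 14 cases (9 adjusted over the list alone; list adjusted p = 7.88e-14, which held with an estimated correlation), and in 0 of 14 in series Z (0 adjusted over the list alone; 0.344). Taken gene by gene, the median difference between the series (M minus Z) was 3.49. The list test of that difference held with both correlations (list adjusted p = 3e-11, and adjusted p = 0.000985 with an estimated correlation). stab2 was higher by 5.69 ± 1.01 in series M and gave 0.49 ± 0.85 (adjusted p = 0.9) in series Z, and mrc1a by 5.74 ± 0.97 and 0.63 ± 0.80 (adjusted p = 0.85). flt4 gave 2.52 ± 0.92 (adjusted p = 0.11) and 0.36 ± 0.84 (adjusted p = 0.94). Endothelial genes were higher in 8 of 19 cases in series M (13 adjusted over the list alone; 5.33e-08, and adjusted p = 0.0547 with an estimated correlation), kdrl by 3.46 ± 0.87 and cdh5 by 3.27 ± 0.77. In series Z 0 of 20 were (0 adjusted over the list alone; 0.615), with kdrl at 0.24 ± 0.77 (adjusted p = 0.96). The test of that difference gave a list adjusted p = 3.65e-06 and was lost at an adjusted p = 0.0619 with an estimated correlation. Arterial genes passed in series M (5 of 13 higher, 5 adjusted over the list alone; 0.0304, and adjusted p = 0.136 with an estimated correlation) and gave 0.399 in series Z, but the difference did not pass (list adjusted p = 0.18).

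Of the remaining lists for CVP against CV, none held with an estimated correlation. Neutrophil genes were higher in 3 of 9 and 3 of 11 cases (4 and 7 adjusted over the list alone; list adjusted p = 0.00356 and 1.07e-08; adjusted p = 0.0862 and 0.0944 with an estimated correlation). Niche factors were higher in 4 of 13 and 2 of 12 cases, with 1 lower in series Z (7 and 4 higher adjusted over the list alone; 0.00849 and 0.0309; adjusted p = 0.0547 and 0.23 with an estimated correlation). ccl25b was higher by 5.22 ± 1.27 in series M and gave 1.11 ± 1.33 (adjusted p = 0.84) in series Z. Muscle genes were higher in 10 and 0 of 24 cases (20 and 0 adjusted over the list alone; 1.06e-12 and 0.000878; adjusted p = 0.0565 and 0.549 with an estimated correlation). Epidermal genes were lower in 4 of 16 and 0 of 15 cases (11 and 6 adjusted over the list alone; 1.8e-15 and 1.06e-10; adjusted p = 0.0547 and 0.176 with an estimated correlation), and ribosomal protein genes in 2 of 88 and 0 of 87 (2 and 0 adjusted over the list alone; 6.87e-13 and 2.98e-29; adjusted p = 0.219 and 0.116 with an estimated correlation). In series M erythroid (2 of 16 higher, 5 adjusted over the list alone; 0.000363) and glycolytic genes (5 of 16 higher, 7 adjusted over the list alone; 0.0392) passed, with adjusted p = 0.258 and 0.227 with an estimated correlation. In series Z blood stem cell (0.0349), cell cycle (0.00548) and oxidative phosphorylation genes (1.02e-05) passed with 0 called members (0 adjusted over the list alone), the first 2 as higher and the last as lower, with adjusted p = 0.285, 0.384 and 0.285 with an estimated correlation. The other 10 lists gave list adjusted p from 0.309 to 0.972 in series M and from 0.344 to 0.745 in series Z.

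Both series shared 8 genes higher and 19 lower in CVP, against 1.47 and 0.271 for independent lists. Of the called genes 86.6% and 45.2% were higher as deposited, and 63.6% and 25% after quantile scaling (208 higher and 119 lower in series M, 15 and 45 in series Z), which moved the median of all genes from 0.56 to 0 and from 0.27 to 0.03. The count of series M fell from 895 to 488 at equal depth, 401 with limma-voom, 66 with detected genes as a covariate, and 593, 438, 413 and 491 without layers 2, 6, 8 and 12, and rose to 1471 without layer 17. That of series Z fell from 73 to 37 with a pseudocount of 0.1, and to 33, 34 and 48 without layers 1, 10 and 22.

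Left and right muscle served as a contrast between like tissues. limma called 0 genes in series M, where 207 had an unadjusted p under 0.05 (1.1%) and limma-voom called 0. In series Z it called 2, both higher in L: six2b, a homeobox gene, and fgf13a, a member of the fibroblast growth factor family, were listed at 0 in all 6 R libraries and had reads in 4 and 5 of the 5 L libraries (adjusted p = 0.005 and 0.044). In series Z 607 genes had an unadjusted p under 0.05 (3.7%), and limma-voom called 0. actc1b gave -0.02 ± 0.54 (adjusted p = 1) and 0.23 ± 0.94 (adjusted p = 1). With the preset correlation 3 lists passed in series M, erythroid genes as higher in L (0.0129) and epidermal (0.0239) and ribosomal protein genes (1.39e-07) as lower. In series Z 4 passed, all as lower in L: stromal (0.00936), erythroid (1.39e-05), notochord and cartilage (0.0249) and oxidative phosphorylation genes (0.0249). No member was called, with 2 erythroid genes lower in series Z adjusted over the list alone, and the erythroid median was 0.79 in series M and -0.86 in series Z, so that this list went opposite ways. The adjusted p with an estimated correlation was 0.901 for the 3 lists of series M and 0.831 to 0.941 for the 4 of series Z. Without layer 1, 10, 22 or 25 series Z gave 0 genes, and without layer 19 it gave 1.

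The last comparison asked whether genes of the CHT changed along the layers of a series. limma called 0 genes in series M (1000 with an unadjusted p under 0.05, 5.5%) and 0 in series Z (1800, 10.9%), over 6 section means each. mrc1a changed by 0.10 ± 0.09 per layer (adjusted p = 0.91) in series M and -0.01 ± 0.03 (adjusted p = 0.97) in series Z, and actc1b by -0.21 ± 0.06 (adjusted p = 0.85) and -0.08 ± 0.03 (adjusted p = 0.4). With the preset correlation, epidermal genes passed as rising (6.35e-05) and muscle genes as falling (6.97e-08) in series M, with 0 members called (0 adjusted over the list alone), and the adjusted p with an estimated correlation was 0.954 for both. The epidermal call rested on layer 17, the last section, whose CA and CVP libraries stood far above the others on that list, and was lost without it (list adjusted p = 0.933). In series Z erythroid genes passed as rising (0 of 17 members, 14 adjusted over the list alone; 6.38e-15), and posterior hox genes, which pattern the hind end of the body axis, did too (0 of 13 members, 9 adjusted over the list alone; 1.26e-05). Their adjusted p was 0.439 and 0.177 with an estimated correlation. Oxidative phosphorylation (17 rising adjusted over the list alone; 2.25e-09) and ribosomal protein genes (7.14e-10) also passed there as rising, and muscle (3 falling adjusted over the list alone; 1.83e-06) and neutrophil genes (0.0256) as falling, with adjusted p = 0.439, 0.755, 0.578 and 0.712 with an estimated correlation. The neutrophil call was also lost without layer 10, 19 or 22 (list adjusted p = 0.105, 0.0712 and 0.231). In series Z the depth rose with the layer number as well, with r = 0.936 in the CHT. Changes set into simulated data of this size were seldom recovered: of 100 genes with an end-to-end log2 change of 4, the test found 1% in series M and 8% in series Z. After quantile scaling 68 genes were called in series Z (64 rising), and without layer 1, 6, 10 or 22 there were 39, 5, 4 or 1.

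A joint fit of both series then tested which region differences differed between M and Z. It was not repeated at equal depth, so a part played by depth was not tested. Libraries of series Z were deeper, in CA with 1075972.7 reads on average against 155019.7 in series M, and in N with 1304259.8 against 634544.3. In the CHT against surrounding tissue 132 genes differed, 121 of them with the higher change in series Z. The median difference over the erythroid genes was -3.78 (series M minus series Z, list adjusted p = 1.02e-29, and adjusted p = 0.000489 with an estimated correlation). hbbe3, an embryonic beta globin gene, differed by -6.49 (adjusted p = 3.91e-05) and slc4a1a, the anion exchanger of red cells, by -5.56 (adjusted p = 2.44e-05). The median difference over the neutrophil genes was -1.68 (list adjusted p = 2.58e-05, and adjusted p = 0.0459 with an estimated correlation). For CVP against CV 30 genes differed, 28 with the higher change in series M, among them aplnra, an apelin receptor gene of veins, by 6.25 (adjusted p = 0.000541). For CV against CA 29 genes differed and for CVP against CA 7. For N against muscle limma called 0 genes, with 805 at an unadjusted p under 0.05, and for L against R 0, with 290. Of 138 list differences, 37 passed with the preset correlation and 3 with both. A list that passed in 1 series and not in the other does not by itself make a difference between them.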

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

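Among the tests below, those of equal depth, vessel wall and skin share in the CV captures and swapped labels in layer 17 were chosen after the result was seen. The tests of the highest genes, the strongly expressed genes and skin inside the layer 17 captures had bounds set before their values were seen, though after the patterns were. The skin test took the place of an earlier one on the epidermal list itself, which had met its bound for skin but was set aside because that list had shown the pattern. The bounds of the replacement were set after that earlier value was seen.

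Of 90 groups of libraries tested for a library far from the others, 12 held one. The bound is meant to flag about 1 in 20 by chance. Where all other libraries of a group stood at 0, any value above 0 is flagged, so that rate does not apply there. In layer 17 of series M, and2 stood at 10.3 in CA (log2 level, 0 in each of the other 5) and at 11.5 in CVP (others 2.68 to 5.68). cxcl12a stood at 2.33 in CA (others 6.37 to 8.55) and at 2.06 in CV (others 0), cxcl12b at 2.96 in CV (others 0), and actc1b at 15.5 in R (others 16.2 to 16.7). Elsewhere in series M, actc1b stood at 10.3 in N of layer 2 (others 5.49 to 7.16), mpx at 6.9 in CA of layer 2 (others 0) and hbae3 at 0 in CVP of layer 12 (others 8.53 to 11.9). In series Z, hbae3 stood at 13.9 in CA of layer 10 (others 16.3 to 17.5), kdrl at 7.29 in CV of layer 10 (others 5.91 to 6.3) and krt4 at 12.3 in CV of layer 25 (others 13.5 to 14).

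The joint fit, which was not repeated at equal depth, gave 12 of 407 named gene differences between the series. In the CHT against surrounding tissue the change in series M minus that in series Z was -5.46 for hbae3 (adjusted p = 0.0124), -3.54 for hbae1.3 (0.043), -6.49 for hbbe3 (3.91e-05), -5.56 for slc4a1a (2.44e-05), -5.14 for alas2 (0.000764) and -3.67 for gata1a (0.00055). It was -2.84 for aplnra (0.00465) and -3.29 for srgn, a granule proteoglycan gene of blood cells (0.0193). In CVP against CV it was 6.04 for stab1 (0.00422), 6.25 for aplnra (0.000541), 4.62 for lyve1b (0.0203) and 5.72 for gpr182 (0.0253), and lyve1b and gpr182 were listed at 0 in all CV libraries of series M. The median of these gene by gene differences over a list was -1.68 (neutrophil) and -3.78 (erythroid) in the CHT and 3.49 (venous scavenger) in CVP against CV.

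In N against muscle most called genes were higher in N. Deeper N libraries are argued against, since 92% (series M) and 90.8% (series Z) were higher in N after every library was thinned to 75000 reads. A loss of weakly expressed transcripts from muscle is argued against as the whole cause. The share was 83.3% and 83.8% among the 4566 and 4137 genes with the highest mean level. A few genes taking most muscle reads stay open as a cause. Without the 50 highest genes of each library the share was 91.7% and 89.1%. The remaining values were still scaled to the full library total, so this test could not remove the effect of those genes. A wider difference in RNA composition, which quantile scaling removes in part (60.8% and 65.1%), may also stand behind the pattern. A difference between the tissues themselves stays open as untested.

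In series M venous scavenger genes were lower in CV than in CVP, and endothelial genes were too with the preset correlation (list adjusted p = 5.33e-08, lost at an adjusted p = 0.0547 with an estimated correlation). Deeper CVP libraries are argued against, since the median change of both endothelial lists was 2.61 with equal reads and 2.54 without. More skin in the CV captures of series M than in those of series Z did not show in the epidermal levels, which were 0.04 apart with an SD of 0.79 and 0.46. Each level averages the epidermal genes tested in its own series, and these sets were not the same, so the gap does not settle it. Less vessel wall inside the CV captures of series M stays open, since the lower endothelial list in CV than in CA there (median -2.43, against -0.32 in series Z) rests on the same CV libraries, and that difference between the series was lost at an adjusted p = 0.24 with an estimated correlation. A difference between M and Z as such stays open and untested, since the labels do not say what they are.

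In layer 17 of series M the CA and CVP libraries held epidermal and fin fold transcripts, and the muscle captures were also the highest of their regions on the epidermal list (6.24 in L, others 1.06 to 5.55; 7.12 in R, others 3.03 to 6.62), with and2 at 4.38 in R (others 0). A full swap of the CA and CV labels is argued against on the notochord and cartilage list, where the library labelled CA stood at 4.33. That lies inside the 1.95 to 4.84 of the other CA libraries and above the 0.67 to 1.56 of the other CV libraries. Other values went the other way, so a swap is not excluded. On the arterial list the library labelled CV stood at 2.88 (others 0.70 to 1.13) and that labelled CA at 3.22. Exchanging the labels of layer 17 gave 541 genes for CV against CA, against 488 as labelled. An exchange of the CV and CVP labels stays open. Fitted as 1 of the splits described below, it gave 1182 genes for CVP against CV, against 895 as labelled. On the venous scavenger list the library labelled CV stood at 3.08 (others 0.91 to 2.04) and that labelled CVP at 4.66 (others 5.44 to 6.43). Skin and fin fold tissue inside the CA and CVP captures could account for the pattern, but the test left it open. Of 544 genes higher in CV than CA in series Z, 48.9% lay above all other libraries of the region in CA and 40.3% in CVP (15.6% and 12.4% of all genes), between the bounds of 25% and 50% set for it. No biological explanation was tested.

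Other splits of the same libraries within sections were fitted to see whether chance could give as many called genes. For CHT against surrounding tissue, 1 of 100 splits, the real one, reached 3255 genes in series M (highest other 169). In series Z 1 of 100 reached 3631 (128), so the real split was the highest of those tried in both. The same held for N against muscle, with 1 of 100 at 9571 (4490) in series M and 1 of 100 at 7502 (4928) in series Z. It held for CVP against CA, with 1 of 32 at 615 (361) and 1 of 32 at 737 (183), and in series Z for CV against CA, with 1 of 32 at 712 (183), and CVP against CV, with 1 of 32 at 73 (26). For these 1 in 32 was the lowest share possible, and no share was adjusted over the comparisons. The splits also take sections as independent, which the labels do not settle, so being the highest does not by itself exclude chance.

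In series M, CV against CA gave 488 genes and 2 of 32 splits reached that many, the highest other with 541. CVP against CV gave 895, and again 2 of 32 reached it, with 1182. The real split was therefore the highest in neither case, and this measure gives nothing against chance for these counts. In both cases the other split exchanged the regions of layer 17 alone, the section whose CA and CVP libraries stood apart. Without that section the counts were 685 and 1471. For L against R, 32 of 32 splits reached the 0 of series M (highest other 1). In series Z the 16 splits were too few for a share under 0.05, with 2 of them reaching the real count of 2 and a highest other of 2. The layer trend of 0 genes was reached by 100 of 100 orders of the sections in both series (highest other 0 in series M and 9 in series Z, out of 720 orders). Any split or order reaches a real count of 0, so where that was the count the splits say nothing about chance.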

How the results depend on the processing

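The fits with limma-voom, equal depth, without the CA library of layer 17 and with the averaged library were chosen after the data were seen, and all others were planned. Among named genes and lists 9 directions reversed, 1 of them the sign of a list test whose median stayed positive, and no count of called genes moved by over 1.5 times without the filter, without the section block, with the rank of the layer, without the CA library of layer 17 or with the averaged library. Without the block, which pairs the regions of a section, series M and Z gave 3232 and 3509 genes for the CHT, 9517 and 7129 for N against muscle, 453 and 645 for CV against CA, 600 and 680 for CVP against CA, 882 and 73 for CVP against CV, and 0 and 2 for L against R. The cause of the moves below was not tested, except that leaving out a section or thinning reads leaves less data. Exact permutation of labels gene by gene was not run, since 6 pairs cannot give a p that passes the adjustment, and the counts of splits stand in its place. Shallow libraries list many genes at 0, so weakly expressed genes in CA and CV of series M are the least certain.

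Detected genes as a covariate gave 2083 genes for the CHT in series M (3255 reported), 438 and 1575 for N against muscle in M and Z (9571 and 7502), 466 for CV against CA in Z (712), 38 and 196 for CVP against CA (615 and 737) and 66 for CVP against CV in M (895). It gave 281 shared genes for N against muscle (5926), 8 for CVP against CA (107) and 1 for CVP against CV (27). This covariate differs between regions, so it removes part of the difference itself. Quantile scaling gave 3414 and 3427 for N against muscle, 191 and 328 for CVP against CA, 327 for CVP against CV in M, 68 for the layer trend in Z (0), and 2238 and 44 shared genes for N against muscle and CVP against CA. limma-voom gave 10766 for the CHT in M, 289 for CV against CA, 222 for CVP against CA and 401 for CVP against CV in M, and 0 for L against R in Z (2). Equal depth gave 320 and 463 for CVP against CA, 488 for CVP against CV in M, 1 for L against R in Z and 51 shared genes for CVP against CA. A pseudocount of 0.1 gave 37 for CVP against CV in Z (73) and 16 shared genes (27). Lists called the same way in both series fell from 46 to 22 with an estimated correlation.

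With each section left out in turn, series M gave 2385 to 2694 genes for the CHT, 7841 to 8336 for N against muscle, 301 to 685 for CV against CA (301 without layer 6, 315 without 8), 224 to 915 for CVP against CA (365, 277, 224 and 343 without 2, 6, 8 and 12), 413 to 1471 for CVP against CV (593, 438, 413, 491 and 1471 without 2, 6, 8, 12 and 17) and 0 for L against R and the trend. Series Z gave 2579 to 3586, 5814 to 6866, 480 to 659, 405 to 717 (405, 475, 439 and 471 without 1, 10, 19 and 22), 33 to 77 (33, 34 and 48 without 1, 10 and 22), 0 to 3 for L against R (0 without 1, 10, 22 or 25, 1 without 19) and 0 to 39 for the trend (39, 5, 4 and 1 without 1, 6, 10 and 22). Shared genes ran from 1343 to 1587 (CHT), 4785 to 5578, 132 to 240, 47 to 146 for CVP against CA (58, 47 and 61 without M layers 6, 8 and 12) and 13 to 33 for CVP against CV (15, 13 and 15 without M layers 6, 8 and 12, and 16 without Z layer 10).

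The reversals were in N against muscle. With detected genes as a covariate the test of the erythroid list in Z turned from negative to positive, while its median was 0.502 before and 0.781 after. The other values with this covariate were -0.054 for cd74a and -0.213 for hspa5 in Z, and -0.592 for stat1a and -3.367 for cdx4 in M. With quantile scaling they were -0.303 (M) and -0.146 (Z) for rps6ka3b, 0.305 for rplp0 and -0.368 for cdh5 in Z. Of the other named gene and list values, the covariate kept 434 on their side of the threshold and weakened 209, quantile scaling 520 and 126, limma-voom 491 and 67, equal depth 558 and 79, the pseudocount 585 and 65, no filter 605 and 45, and no block 624 and 24.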

Other observations

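The lists for pigment cells, actinodins, fin fold, lysosome, glia, ionocytes and mucous or lateral line cells were made after the main results were seen. The tests on melanophore genes, on actinodins and iridophore genes and on posterior hox genes against layer number were chosen only after the result was seen. Fin fold genes and the hox relation at equal depth had their tests set before their values were.

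Melanophore genes, among them tyrp1b and dct of the melanin pathway, were higher in the CHT than around it in 11 of 12 cases in series M and 12 of 12 in series Z (list adjusted p = 5.6e-11 and 1.6e-11). In CVP against CA 9 and 11 of 12 were higher, and in CV against CA 2 and 10 of 12 (list adjusted p = 2.76e-05 and 8.33e-15; adjusted p = 0.112 and 0.00857 with an estimated correlation). tyrp1b stood at 10.00 ± 1.04 (log2 level, SD, n = 6) and 10.86 ± 0.72 in CVP and at 2.29 ± 3.79 and 4.46 ± 3.59 in CA. Lysosome genes were higher in the CHT in 5 of 14 and 13 of 15 cases (list adjusted p = 0.000888 and 2.21e-08). Both lists held there with an estimated correlation. The actinodin genes of the fin fold, and1, and2 and and3, were higher in CV than in CA in 3 of 3 cases in both series (median change 6.36 and 9.52; list adjusted p = 3.81e-08 and 1.6e-15) and lower in CVP than in CV in 3 of 3 (median change -5.50 and -7.08).

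Counting tests that passed with both correlations, over 6 region comparisons in 2 series, lysosome genes passed in 4 and fin fold genes in 2. Xanthophore, ionocyte, mucous or lateral line, and glial genes passed in 0, as did iridophore genes, whose list was written after their values were seen. The actinodin and melanophore lists were built around genes already seen to change, so their passes are not set beside these. fbln1 of the fin fold list is also on the stromal list, csf1ra of the xanthophore list on the macrophage list and tfec of the iridophore list on the niche factor list, and sox10 is on both the melanophore and glial lists.

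Pigment cells inside the CVP captures may account for the melanophore genes. Without tyrp1b, dct and slc45a2, which had already stood out, the remaining list of 9 genes was higher in CVP than in CA in both series, by a median of 4.183 (series M; list adjusted p = 1.79e-11, and adjusted p = 0.00267 with an estimated correlation) and 4.68 (series Z; 5.04e-12, and 0.00797). Against CV the medians of these 9 were 2.521 (series M; 0.000265, and 0.0547 with an estimated correlation) and 0.671 (series Z; 0.669), which leaves open whether CVP holds more of them than CV. In series Z tyrp1b in CV stood at 10.38 ± 0.61. No sort or gate would have removed such cells, since capture was by position.

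Fin fold tissue inside the CV captures could likewise account for the actinodins there. A separate list of fin fold matrix genes (9 tested in series M and 8 in series Z) gave a median change from CA to CV of 0.764 in series M (list adjusted p = 0.339) and 1.71 in series Z (0.00656, and adjusted p = 0.12 with an estimated correlation), which does not settle it. From CV to CVP the list median was -0.60 in series M (0.00271, and adjusted p = 0.0578 with an estimated correlation) and -1.12 in series Z (8.74e-06, and adjusted p = 0.0113 with an estimated correlation), with 0 members called, so the list fell with the actinodins in series Z and the question stays open.

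A further hypothesis is that layer numbers run along the tail axis, in which case posterior hox genes may follow them. In series Z the mean level of that list rose with the layer number in the CHT (Pearson's r = 0.982, exact permutation p = 0.00417, adjusted p = 0.0125 over 6 relations; Spearman's rho = 1, p = 0.00278). It rose in muscle (r = 0.987, exact permutation p = 0.00278, adjusted p = 0.0125; rho = 1, p = 0.00278) and in N (r = 0.9, exact permutation p = 0.0181, adjusted p = 0.0362; rho = 0.943, p = 0.0167). Without the 2 layers farthest from the median layer r was 0.992, 0.989 and 0.797. In series M r was 0.316 (CHT), 0.45 (muscle) and 0.63 (N), with exact permutation p = 0.501, 0.344 and 0.193, rho = 0.486, -0.029 and 0.6, and r = -0.444, 0.948 and 0.276 without the 2 farthest layers, so the hypothesis was neither borne out nor excluded there. Reads in series Z rose with the layer number too. Read depth alone is argued against as the cause, since r was 0.952, 0.956 and 0.891 after every library was thinned to 75000 reads. The adjusted exact permutation p was 0.0167, 0.0375 and 0.0472 for r, and 0.0167, 0.0501 and 0.0666 for rho. Thinning does not even out PCR copies. Detected genes at full depth gave r = 0.838 (CHT), 0.874 (muscle) and 0.453 (N) with layer number (adjusted exact permutation p = 0.212, 0.208 and 0.554). Other lists were not tested against layer number in muscle or N.

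Sections were little alike across regions. After the means of each region were removed, libraries of the same section had a mean correlation across genes of 0.010 in series M and 0.024 in series Z, against -0.002 and -0.004 for libraries of different sections, and genes are not independent replicates.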
